A study of Arabidopsis thaliana with 12 samples.

How the data were processed

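Transcript levels were measured on Affymetrix ATH1 arrays hybridised with RNA from the meristematic and the elongation zone of Arabidopsis thaliana roots. The plants were wild-type Col-0, the mutant upb1-1, and the line 35S::UPB1-3YFP #2, which the labels place in the upb1-1 background and which is called OX here. Per the labels' protocols, seedlings were 6 days old, the zones were separated with a razor blade under a microscope, about 60 roots went into each replicate, and the RNA was amplified in a two-cycle procedure before labelling. The 12 arrays form 6 groups of 2 biological replicates.

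The deposited values are linear probe set signal intensities that the authors produced with MAS5, per the submitters' processing notes, which give no version. The values show that each array had been scaled to the same 2% trimmed mean, between 249.881 and 249.899 on every array. No detection calls were used here. The table held 22810 probe sets, of which 64 control probe sets were left out of the tests, leaving 22746.

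Signals were taken to log2 after adding 16, with no further scaling between arrays. The added 16 compresses changes of dim probe sets, so a log2 change of a probe set near the floor is smaller than the ratio of its signals. A probe set was tested if its signal reached the 40th percentile of its array on at least 2 of the 12 arrays, which left 15834 probe sets. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 6 group means, then eBayes with a trend of the variance on mean signal, two-sided). All 12 arrays shared 1 estimate of the spread, and the prior carried 8.75 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 15834 probe sets of each comparison, and a probe set counted as changed at an adjusted p below 0.05. Adjusted p-values of single genes in all parts come from limma. The comparisons were 3 between genotypes in each zone, the zones within each of the 3 genotypes and averaged over them, the genotypes averaged over both zones, and the zone by genotype interactions. With 2 arrays per group, the number of arrays limits the precision.

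Gene names were taken from the platform annotation supplied with the data, which lists 14016 probe sets, and from a gene table of the TAIR10.1 assembly used for names only. Of the tested probe sets, 8866 (56.0%) had 1 named gene, 328 had several, and 6640 are unnamed here, which does not mean that they lack a gene. Where several probe sets gave 1 gene, the one with the highest mean signal stood for it in gene lists. Many members of the gene lists are therefore not covered.

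Gene lists were tested as sets with limma's camera at a preset correlation between genes of 0.01, where at least 3 members were tested, and again with the correlation estimated from the data. The p-values were adjusted over the 96 tests of the fixed lists and, apart from them, over the 352 tests of the added lists. The comparisons, the filter, the scale, the fixed lists, the rule for naming genes and the main alternatives were all chosen before the data were examined. The fixed lists were UPB1, 3 peroxidases remembered as linked to UPB1 by the study itself on these samples, class III peroxidases, NADPH oxidases, antioxidant enzymes (superoxide dismutases, catalases and ascorbate peroxidases), glutathione S-transferases, genes of the G2/M phase, genes of DNA replication and S phase, expansins, xyloglucan endotransglucosylase/hydrolases, and markers of root hairs, stem cell niche, endodermis, xylem, root cap, photosynthesis and wounding. A list of cytokinin and auxin genes of the transition zone was also fixed. The class III list includes the 3 UPB1-linked peroxidases, so its results are not fully independent of the study's choice. The added lists were cytosolic ribosomal proteins, core histones, mitotic kinesins with B-type cyclins, plastid-encoded genes, and 18 families of genes that share a symbol stem. They were drawn up after the counts of changed probe sets and the signals of UPB1, PER39, PER40 and PER57 had been seen, and before the values of their members were. The exception is the list of plastid-encoded genes, which was drawn up after cemA, psaI and rpoC1 had been seen to be high.

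Named genes are UPB1 on every array, up to 8 rises and 8 falls with the largest change for each comparison of genotypes within a zone and for the averaged zone comparison, up to 4 members of each fixed list with the smallest p, the 3 UPB1-linked peroxidases, up to 8 genes that changed in opposite directions in upb1-1 and OX, and up to 5 genes per interaction. The largest changes were taken among changed probe sets with 1 gene whose replicates do not overlap between groups and whose brighter group lies above the median of all tested probe sets. Where fewer than 3 passed, the 3 with the smallest unadjusted p stand in their place and are said not to pass. Genes named outside this rule are marked where they appear. Not all named genes are printed.

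Comparisons of upb1-1 and of OX with Col-0 share the Col-0 arrays, so their overlap was set beside 50 simulations of unchanged groups that share those arrays and beside the overlap of independent lists. The simulations first used 1 pooled spread, and after that run they were changed to the spread of each group. Both results are given. The fitting code was tested on simulated data of 15834 probe sets with 50 changed at each size. In the simulated comparison of upb1-1 with Col-0 in the meristematic zone, 8% of 1.5-fold, 48% of 2-fold, 100% of 4-fold and 100% of 8-fold changes were recovered, with 9 false calls. In the simulated comparison of OX with Col-0 in the elongation zone, the shares were 12%, 42%, 100% and 100%, with 5 false calls. The simulated groups had equal means apart from the planted changes, and 1 pooled spread. The share recovered also depends on how many probe sets change. These shares check the code and are not the power of the real comparisons.

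The alternatives were a pseudocount of 1 or 64, no filter or a filter at the 60th percentile, quantile normalization, median centring, eBayes without a trend, fits of only the arrays compared, the replicate number or the plant pool as a block, and leaving out each array in turn, which assumes that the lone array of a group varies like the other groups. Fits without the OX meristematic arrays, fits of the elongation arrays alone, the restriction of the meristematic OX comparison to probe sets changed the same way in the elongation zone, the comparison of changes with 1 Col-0 array each, and splits that hold zones or genotypes evenly were added after the data had been seen. No array was left out of the main comparisons.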

Results

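RNA of the meristematic and the elongation zone was profiled in 6-day-old roots of Col-0, upb1-1 and OX, with 2 biological replicates in each of the 6 groups. Median signals of the 12 arrays lay between 50.8 and 67.6, and the brightest probe set of each array lay between 9484 and 16433. Replicates correlated across probe sets with Pearson's r between 0.966 and 0.989, and genes are not independent replicates. The spread between replicates (SD on the log2 scale) was 0.20 for upb1-1 meristematic, 0.22 for Col-0 meristematic, 0.27 for OX meristematic, 0.29 for OX elongation, 0.30 for Col-0 elongation and 0.36 for upb1-1 elongation arrays. The first principal component held 52.9% of the variance and the next 26.3%.

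The 3' to 5' signal ratio of the GAPDH, actin and ubiquitin controls, a sign of RNA length, differed between groups. The RNA was amplified before labelling, so the ratio does not separate the length of the input RNA from that of the amplified product. Its mean log2 value was 2.22 on Col-0 and 2.04 on upb1-1 meristematic arrays and 4.17 on OX meristematic arrays. On the elongation arrays it was 3.93 for Col-0, 4.04 for upb1-1 and 3.97 for OX.

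**Figure D1:**
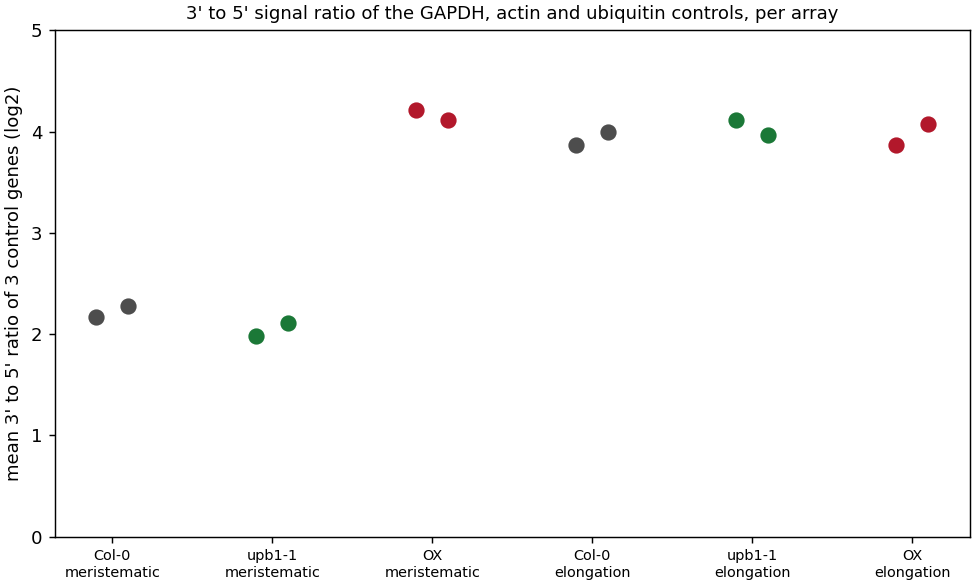
Mean log2 ratio of 3' to 5' signal over the GAPDH, actin and ubiquitin controls, with 1 point per array and 2 arrays per group. The Col-0 and upb1-1 meristematic arrays sit between 1.98 and 2.27, the OX meristematic arrays at 4.12 and 4.21, and the elongation arrays between 3.87 and 4.12.

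UPB1 (AT2G47270), a gene for a basic helix-loop-helix transcription factor and the target of the mutation and the transgene, gave signals of 667 and 528 on the Col-0 meristematic arrays and 1379 and 1233 on the Col-0 elongation arrays. The upb1-1 arrays gave 8.53 and 16.8 in the meristematic and 11.9 and 15.6 in the elongation zone. The OX-labelled arrays gave 28.1 and 55.2 in the meristematic and 53.6 and 35.3 in the elongation zone. Relative to Col-0, UPB1 fell by 4.43 (log2, adjusted p = 3.06e-07) in upb1-1 and by 3.44 (adjusted p = 1.1e-07) on the OX-labelled arrays in the meristematic zone. In the elongation zone it fell by 5.47 (adjusted p = 3e-08) and by 4.46 (adjusted p = 5.01e-07). The low OX signal goes against the label of a line that expresses UPB1 from a strong promoter. Whether this probe set lies within the transgene transcript is not given in the sources used here, so it does not check the OX label. OX below stands for the arrays labelled OX.

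The OX-labelled arrays were above the upb1-1 arrays in UPB1 signal by 1.00 (log2, SE 0.18) averaged over both zones (adjusted p = 0.00041). Within zones the difference was 0.98 in the meristematic zone (adjusted p = 0.00548) and 1.01 in the elongation zone (adjusted p = 0.0113). The UPB1 call in the meristematic zone was lost without upb1-1 replicate 1 (0.77, adjusted p = 0.0689) and without OX replicate 2 (0.64, adjusted p = 0.0888), and in the elongation zone without OX replicate 1 (0.79, adjusted p = 0.101). In Col-0, UPB1 was higher in the elongation than in the meristematic zone by 1.11 (adjusted p = 0.00335).

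**Figure D2:**
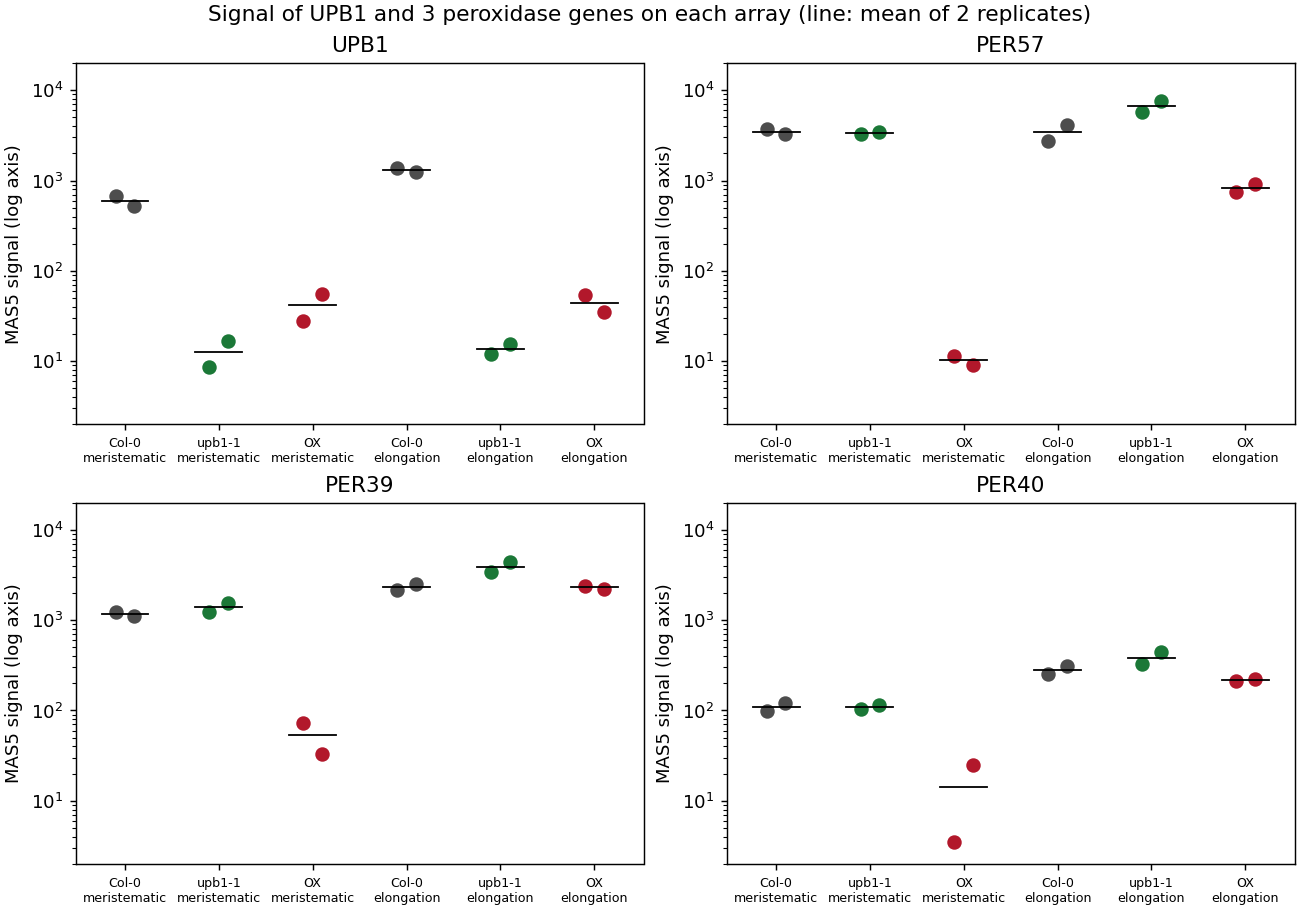
MAS5 signal (log axis) of UPB1 and the peroxidase genes PER57, PER39 and PER40 on each of the 12 arrays, with 1 point per array and a line at the mean of 2 replicates. UPB1 lies at or below 55.2 on all upb1-1 and OX-labelled arrays, and PER57 lies at a mean of 10.2 on the OX meristematic arrays against 3481 on the Col-0 meristematic arrays.

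The comparison of upb1-1 with Col-0 in the meristematic zone asks which genes respond to loss of UPB1 in the pieces cut as that zone. These pieces may not be dividing cells alone. The root hair markers EXPA7 and EXPA18 had mean signals of 494 and 350 on the Col-0 meristematic arrays, against 229 and 65.6 on the Col-0 elongation arrays. In total 6 probe sets changed, 2 higher and 4 lower, with 264 at an unadjusted p below 0.05, and 16 changed when only these 4 arrays were fitted. AT3G55920 was 4.64 higher (log2, SE 0.18, adjusted p = 1.85e-09), from a signal of 4.28 ± 2.00 in Col-0 to 488 ± 24.0 in upb1-1 (SD, n = 2). This gene was low on the Col-0 meristematic arrays alone, since its signal was 248 ± 45.2 on OX meristematic arrays and 879 ± 87.3 on Col-0 elongation arrays. Besides UPB1, the falls with a named gene were AT5G09570, by 1.94 (adjusted p = 0.0066), and QQS, a gene that affects starch content, by 1.86 (adjusted p = 0.0127). The remaining rise and the remaining fall were those of probe sets unnamed here.

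Leaving out any 1 of the 4 meristematic Col-0 and upb1-1 arrays ended the calls of AT5G09570 and QQS. Without Col-0 replicate 1, upb1-1 replicate 1 or upb1-1 replicate 2, 3 probe sets changed in this comparison. AT5G09570 then gave -1.94 without Col-0 replicate 1 (adjusted p = 0.165), -1.94 without Col-0 replicate 2 (0.123), -2.04 without upb1-1 replicate 1 (0.0916) and -1.84 without upb1-1 replicate 2 (0.194). QQS gave -2.01 (0.165), -1.71 (0.282), -1.62 (0.427) and -2.10 (0.060) in the same order. The rises of AT1G48070 (1.01), AT4G04750 (0.89) and AT3G13650 (0.76) did not pass the test.

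None of the 33 tested class III peroxidases, secreted enzymes that use hydrogen peroxide, passed in the meristematic zone of upb1-1 by limma over all probe sets, and 1 was lower adjusted over the list alone. The list gave a median of -0.06 and adjusted p = 0.156 in camera, which became 0.0342 without upb1-1 replicate 2. PER69 had the smallest p, with a change of -1.02 (adjusted p = 0.592). The 3 UPB1-linked peroxidases, which the study chose on these samples and which are therefore not independent evidence, gave 0.24 for PER39, -0.01 for PER40 and -0.06 for PER57, and none passed. Their list median was -0.01 and its mean 0.06, which differ in sign, and the set test gave an upward direction with adjusted p = 0.646.

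Among the wall and oxidase genes, none of the 5 tested xyloglucan endotransglucosylase/hydrolases (enzymes that cut and rejoin wall xyloglucan) passed in upb1-1 meristems, nor adjusted over the list alone. Their median was 0.32, and the set passed camera at adjusted p = 6.77e-05 but not with an estimated correlation (adjusted p = 0.0786). The 3 tested NADPH oxidases, which make superoxide outside the cell, had a median of -0.54 with none passing, also adjusted over the list alone. That set passed at adjusted p = 0.0235 with the preset but not with an estimated correlation (adjusted p = 0.185). It did not pass without Col-0 replicate 2 (adjusted p = 0.107) or without upb1-1 replicate 1 (adjusted p = 0.0653). None of the 9 tested expansins or the 3 tested G2/M genes passed, and neither set did (adjusted p = 0.175 and 0.608).

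The comparison of OX with Col-0 in the meristematic zone sets pieces of the line labelled as overexpressing UPB1 against those of Col-0. The UPB1 signal of that line was 3.44 (log2) below Col-0 there. Many peroxidase and wall genes were far lower on the OX-labelled arrays. PER57 fell by 7.06 (log2, SE 0.21, adjusted p = 3e-11), from 3481 ± 299.8 in Col-0 to 10.2 ± 1.71 in OX (SD, n = 2). PER7 fell by 6.08, from 1246 ± 16.6 to 2.72 ± 0.887, and PER45 fell by 5.49, from 6279 ± 263 to 132 ± 66.9. The 2 tested root hair markers, the expansins EXPA7 and EXPA18, fell by 4.27 and fell by 3.79. The 3' to 5' control ratio was 1.95 higher (log2) on the OX than on the Col-0 meristematic arrays, a difference that all gene groups of this comparison share.

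In total 7834 probe sets changed in OX meristems, 4112 higher and 3722 lower, and 8926 had an unadjusted p below 0.05. Of these, 1381 changed in the same direction and 144 in the opposite direction in OX against Col-0 in the elongation zone, where the ratios of the controls differed by 0.04. Independent lists would share 551 and 554. The 1381 were 645 without Col-0 elongation replicate 1 and 517 without OX elongation replicate 1. Restricting the calls to those 1381 was an alternative chosen after seeing the data. The median change of all tested probe sets was 0.10.

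Among class III peroxidases in OX meristems, 21 of the 33 tested members fell, 2 rose and 10 did not pass, and adjusted over the list alone 21 fell and 3 rose. The list median was -1.83, with adjusted p = 1.09e-07 in camera and adjusted p = 0.0628 with an estimated correlation. PER69 fell by 4.60. PER27 fell by 5.77, from 5602 ± 41.2 to 147 ± 178 (SD, n = 2), with -7.26 without OX replicate 1 and -4.28 without OX replicate 2. All 3 UPB1-linked peroxidases fell, with changes of -4.16 for PER39, -2.16 for PER40 and -7.06 for PER57. They were chosen by the study on these samples and are not independent evidence. They are also among the 33 class III members counted above. Adjusted over their own list alone 3 fell. Their set gave adjusted p = 0.000332, and 0.0628 with an estimated correlation. These falls came with a control ratio of 4.17 on the OX against 2.22 on the Col-0 meristematic arrays.

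Several wall genes fell as well in OX meristems. Of 9 tested expansins, which loosen cell walls, 5 fell and 1 rose, the same counts as adjusted over the list alone, and EXPB1 fell by 4.70 and EXPA9 fell by 1.42. The expansin set passed at adjusted p = 0.0372 but not with an estimated correlation (adjusted p = 0.19). Of 5 tested xyloglucan endotransglucosylase/hydrolases 4 fell, and 5 adjusted over the list alone, with -4.70 for XTH18, -4.14 for XTH21, -3.10 for XTH16 and -2.75 for XTH19. Their set gave adjusted p = 7.02e-05, and 0.0786 with an estimated correlation. The NADPH oxidase genes RBOHG and RBOHE gave -2.18 and -1.58 and passed, RBOHI gave -0.68 without passing, and adjusted over the list alone 2 of 3 fell (set adjusted p = 0.061). These groups, too, lie on arrays with the higher 3' to 5' ratio.

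Single cell cycle and stem cell genes were higher in OX meristems. Of 3 tested G2/M genes, AUR1, an Aurora kinase, rose by 0.86, BUBR1, a spindle checkpoint gene, rose with adjusted p = 0.00978, and AUR2 gave 0.63 (adjusted p = 0.0556), with 3 higher adjusted over the list alone. The set did not pass (adjusted p = 0.135). In the added lists, mitotic kinesins with B-type cyclins (11 genes) had a median of 0.19 and core histones (8 genes) of -0.39. The median of all tested probe sets was 0.10. The BUBR1 call was lost without Col-0 replicate 2 (1.03, adjusted p = 0.0639) or OX replicate 1 (0.93, adjusted p = 0.08). BBM, a transcription factor of the stem cell niche, rose by 1.12, while CR4 gave 0.38 (adjusted p = 0.373). These arrays carried the higher 3' to 5' ratio.

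Of the DNA replication genes, PRL, a subunit of the replicative helicase, rose by 0.52 (adjusted p = 0.0314) in OX meristems and ICU2, a DNA polymerase subunit, gave -0.19 (adjusted p = 0.507). Leaving out any 1 of the 4 arrays ended the PRL call, with 0.60 without Col-0 replicate 1 (adjusted p = 0.0672), 0.44 without Col-0 replicate 2 (0.168), 0.55 without OX replicate 1 (0.0835) and 0.49 without OX replicate 2 (0.12). Other single markers were GSO1, a receptor kinase of the endodermal barrier, which fell by 1.90, SAPX, an ascorbate peroxidase, which fell by 0.82, and STZ, a stress-induced zinc finger gene in the wounding list, which rose by 2.00. TAPX gave 0.09 (adjusted p = 0.831). These arrays, too, carried the higher 3' to 5' ratio.

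The glutathione S-transferase GSTU25 fell by 0.47 (adjusted p = 0.0236) in OX meristems. That call was lost without Col-0 replicate 1 (-0.41, adjusted p = 0.134), Col-0 replicate 2 (-0.52, 0.0647) or OX replicate 2 (-0.37, 0.155). The light-harvesting gene LHCB4.1 fell by 0.69 (adjusted p = 0.046), a call lost without Col-0 replicate 1 (-0.89, 0.0532), Col-0 replicate 2 (-0.49, 0.273), OX replicate 1 (-0.68, 0.129) or OX replicate 2 (-0.71, 0.116), and under quantile normalization (0.0598) or median centring (0.0677). The 3' to 5' control ratio was higher on these OX arrays as well.

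The rises of OX meristems among single genes included AT5G01870, by 4.39 from 3.84 ± 0.377 to 410.2 ± 132 (SD, n = 2), AT5G05250 by 4.17, and AT3G55920 by 3.69, the gene that was low on the Col-0 meristematic arrays alone. The glycosyltransferase gene UGT87A2 rose by 2.89, from 53.3 ± 9.90 to 496 ± 71.2. Other large falls were AT2G30930 (-6.42) and AT5G44020 (-7.19, with -8.13 without OX replicate 1 and -6.25 without OX replicate 2).

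Against upb1-1, its stated background, OX in the meristematic zone compares the labelled line with plants without its transgene. Single peroxidase and wall genes were lower in OX here, with log2 changes of -5.99 for PER7, -4.95 for XTH18 and -4.99 for EXPB1, and IAGLU, a glucosyltransferase of auxin, higher by 2.77. In total 8226 probe sets changed, 4349 higher and 3877 lower. Of the class III peroxidases 21 fell and 2 rose, also adjusted over the list alone (median -1.77, and -1.13 without OX replicate 2), with adjusted p = 2.94e-07 and 0.0628 with an estimated correlation. All 5 tested xyloglucan endotransglucosylase/hydrolases fell, also adjusted over the list alone (adjusted p = 3.98e-05, and 0.0786 with an estimated correlation). The 3' to 5' control ratio of 4.17 on the OX arrays stood against 2.04 on the upb1-1 meristematic arrays.

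The comparison of upb1-1 with Col-0 in the elongation zone asks which genes respond to loss of UPB1 in the pieces cut as that zone. Several peroxidase genes and both tested root hair markers were higher. PER35 rose by 5.10 (log2, SE 0.27, adjusted p = 5.12e-08), from 5.22 ± 4.44 in Col-0 to 726 ± 251 in upb1-1 (SD, n = 2). PER7 rose by 3.66, from 341 ± 185 to 4340 ± 1715, and PER44 by 3.36. The root hair markers rose, EXPA18 by 3.62 and EXPA7 by 2.64, and GH9C1, a glycosyl hydrolase of the endoglucanase family, rose by 3.60 (4.23 without upb1-1 replicate 1 and 2.97 without upb1-1 replicate 2).

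In total 2979 probe sets changed between upb1-1 and Col-0 elongation arrays, 1482 higher and 1497 lower (1442 and 1553 after quantile normalization, 1272 and 1791 after median centring), with 5285 at an unadjusted p below 0.05. The count was 531 without Col-0 replicate 1, 722 without upb1-1 replicate 2 and 4745 without upb1-1 replicate 1. It was 757 when only these 4 arrays were fitted and 1263 when only elongation arrays were, an alternative chosen after seeing the data. Control ratios differed by 0.11 between these groups. On the first principal component upb1-1 replicates 1 and 2 lay at 62.0 and 96.0.

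Of the class III peroxidases, 12 rose in upb1-1 elongation zones, 1 fell and 20 did not pass, against 14 and 2 adjusted over the list alone. The median was 0.28, with adjusted p = 8.53e-05 and 0.0692 with an estimated correlation. Of the UPB1-linked peroxidases, chosen by the study on these samples and so not independent evidence, 2 rose and 1 did not pass, the same counts as adjusted over the list alone. PER57 rose by 0.97 (adjusted p = 0.00645), PER39 by 0.73 (adjusted p = 0.0457), and PER40 gave 0.41 (adjusted p = 0.324). The PER57 call was lost without Col-0 replicate 1 (0.66, adjusted p = 0.106) or upb1-1 replicate 2 (0.77, adjusted p = 0.0666). The PER39 call was lost without Col-0 replicate 1 (0.62), Col-0 replicate 2 (0.83) or upb1-1 replicate 2 (0.55). It was also lost after median centring (adjusted p = 0.0633), with no filter (0.0762), with no trend (0.0836) and at a pseudocount of 1 (0.0937). The same held with only the arrays compared (0.0931) and with the elongation arrays alone (0.0570). The set passed at adjusted p = 0.0371 but not with an estimated correlation (adjusted p = 0.155), nor without Col-0 replicate 1 (0.0783) or upb1-1 replicate 2 (0.0874).

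Of the other fixed lists in the elongation zone of upb1-1, none of the sets tested passed with an estimated correlation. Of 5 xyloglucan endotransglucosylase/hydrolases 4 rose, also adjusted over the list alone, with a set adjusted p = 0.00459, and 0.155 with an estimated correlation. XTH18 was higher by 1.51, and the other 3 calls depended on single arrays. The call of XTH19 (0.81) was lost without Col-0 replicate 1 (0.51, adjusted p = 0.152) or upb1-1 replicate 2 (0.70, 0.0783). That of XTH33 (1.17) was lost without Col-0 replicate 1 (1.31, 0.0676), Col-0 replicate 2 (1.02, 0.0692) or upb1-1 replicate 2 (0.83, 0.174). That of XTH21 (0.82) was lost without Col-0 replicate 1 (0.83, 0.162), Col-0 replicate 2 (0.82, 0.0884) or upb1-1 replicate 2 (0.34, 0.38), and after median centring (0.0502). Of 3 NADPH oxidases RBOHG rose by 1.64 and RBOHE by 1.22, and 3 were higher adjusted over the list alone (set adjusted p = 0.0117, and 0.163 with an estimated correlation). The RBOHG call was lost without Col-0 replicate 1 (1.38, adjusted p = 0.0635) or upb1-1 replicate 2 (1.22, 0.0644). The RBOHE call was lost without Col-0 replicate 1 (1.27, 0.0943), Col-0 replicate 2 (1.17, 0.0553) or upb1-1 replicate 2 (0.73, 0.212). Of 9 expansins 2 rose, also adjusted over the list alone, which are the root hair markers EXPA7 and EXPA18 given above (set adjusted p = 0.0409, and 0.196 with an estimated correlation). Without Col-0 replicate 1 the expansin median went from 0.26 to -0.08 and the set did not pass (adjusted p = 0.115).

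Of the 3 tested G2/M genes, AUR1 fell by 0.83 and AUR2 by 0.91 in upb1-1 elongation zones, and BUBR1 gave -0.42 without passing, with 2 lower adjusted over the list alone (set adjusted p = 0.0579). The AUR1 call was lost without Col-0 replicate 1 (-0.59, adjusted p = 0.223) or upb1-1 replicate 2 (-0.53, 0.214), and the AUR2 call without Col-0 replicate 1 (-0.59, 0.27) or upb1-1 replicate 2 (-0.84, 0.134). GSTU25 fell by 0.61, a call lost without Col-0 replicate 1 (-0.62, 0.0981) or upb1-1 replicate 2 (-0.48, 0.118). GSO1 rose by 1.04, a call lost without Col-0 replicate 1 (1.02, 0.0625) or upb1-1 replicate 2 (0.82, 0.0753). Besides UPB1, the largest falls were AT5G35940 and AT3G10020, with -3.17 each (AT3G10020 -2.52 without Col-0 replicate 1 and -3.82 without Col-0 replicate 2). AT1G54050 fell by 2.87, but gave -5.05 without Col-0 replicate 2, -0.69 without Col-0 replicate 1 (adjusted p = 0.203) and -2.67 without upb1-1 replicate 2 (adjusted p = 0.148).

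The comparison of OX with Col-0 in the elongation zone sets elongation pieces of the same line against those of Col-0. Its UPB1 signal was 4.46 (log2) below Col-0 there. Here, too, several peroxidases were lower on the OX-labelled arrays. PER7 fell by 2.51 (log2, SE 0.30, adjusted p = 0.000239), from 341 ± 185 in Col-0 to 42.3 ± 2.93 in OX (SD, n = 2), PER57 fell by 2.01, from 3445 ± 1009 to 832 ± 123, and PER44 fell by 2.05. Both root hair markers fell, EXPA7 by 2.17 and EXPA18 by 1.91. The 3' to 5' control ratios of these groups were 3.97 and 3.93.

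In total 2234 probe sets changed between OX and Col-0 elongation arrays, 1052 higher and 1182 lower, with 4555 at an unadjusted p below 0.05. The count was 781 without OX replicate 1 and 905 without Col-0 replicate 1, and 780 when only elongation arrays were fitted, an alternative chosen after seeing the data.

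Of the class III peroxidases, 10 fell in OX elongation zones, none rose and 23 did not pass, and 12 fell adjusted over the list alone. The median was -0.34, with adjusted p = 0.00266 and 0.109 with an estimated correlation. Of the UPB1-linked peroxidases, chosen by the study on these samples and so not independent evidence, 1 fell, also adjusted over the list alone, while PER39 gave -0.01 and PER40 -0.34 without passing (set adjusted p = 0.0593). PER56 fell by 1.67, a call lost without Col-0 replicate 2 (-1.31, adjusted p = 0.0623) or OX replicate 2 (-1.22, 0.0679).

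Of 9 expansins 3 fell and 1 rose in OX elongation zones, also adjusted over the list alone, and the set did not pass (adjusted p = 0.287). Their median of 0.07 and mean of -0.41 differ in sign, and the median was -0.03 under quantile normalization. EXPB1 fell by 1.19, a call lost without OX replicate 2 (-0.90, adjusted p = 0.06). EXPA15 rose by 1.06, a call lost without Col-0 replicate 1 (0.95, 0.142), Col-0 replicate 2 (1.17, 0.0568) or OX replicate 1 (0.49, 0.273). None of the 5 xyloglucan endotransglucosylase/hydrolases, 3 NADPH oxidases or 3 G2/M genes passed in limma, nor adjusted over the list alone, and none of these sets did (adjusted p = 0.523, 0.43 and 0.222). LHCB4.1 fell by 1.73.

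TAPX fell by 1.26 in OX elongation zones, a call lost without Col-0 replicate 1 (-1.25, adjusted p = 0.0884), Col-0 replicate 2 (-1.27, 0.0643) or OX replicate 1 (-0.78, 0.175). STZ rose by 1.26, a call lost without OX replicate 2 (adjusted p = 0.0579). Among single genes AT2G04500 rose by 2.26 and cemA, a plastid-encoded gene, by 1.84, from 119.8 ± 18.8 to 473 ± 86.8 (SD, n = 2). AT5G35940 fell by 4.02, and AT3G10020 fell by 4.11 (-3.45 without Col-0 replicate 1 and -4.76 without Col-0 replicate 2), a gene whose Col-0 elongation signal was 736 ± 451 (SD, n = 2). Their falls in upb1-1 were measured against the same Col-0 arrays.

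**Figure D3:**
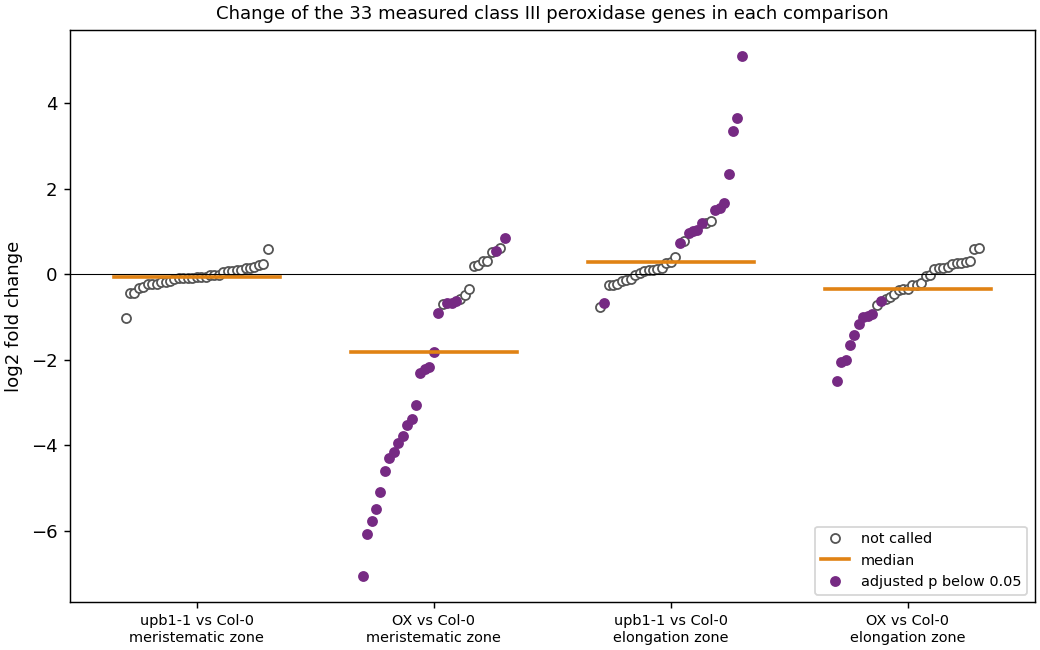
Log2 change of the 33 tested class III peroxidase genes in 4 comparisons, with 1 point per gene, purple where the adjusted p is below 0.05, and a line at the median. The medians are -0.06 and -1.83 in the meristematic zone and 0.28 and -0.34 in the elongation zone, for upb1-1 and OX.

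Against upb1-1 in the elongation zone, single peroxidase and wall genes were lower in OX, with log2 changes of -6.17 for PER7, -5.52 for EXPA18, -5.41 for PER44 and -5.15 for PER35. Of the class III peroxidases 15 fell and none rose, and adjusted over the list alone 16 fell and 1 rose (adjusted p = 7.54e-07, and 0.0628 with an estimated correlation). All 3 NADPH oxidases fell, also adjusted over the list alone (set adjusted p = 0.0066, and 0.155 with an estimated correlation), but RBOHI (-1.31) was not called without upb1-1 replicate 2 (-0.87, adjusted p = 0.239) or OX replicate 1 (-0.79, 0.214), nor RBOHE (-1.46) without upb1-1 replicate 2 (-0.97, 0.0682). AT5G05250 rose by 3.03. In total 3828 probe sets changed, 1830 higher and 1998 lower, a balance that turned with the scaling (2021 and 1990 after quantile normalization, 2104 and 1854 after median centring). The count was 1758 without upb1-1 replicate 2, 2404 without OX replicate 1 and 2484 without OX replicate 2, 1866 when only these 4 arrays were fitted, and 2230 when only elongation arrays were, which was chosen after seeing the data.

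By their labels, upb1-1 and OX form opposite arms of the design, so genes that moved in opposite directions were counted. The signal of the UPB1 probe set was below Col-0 in both (-5.47 and -4.46 in the elongation zone). Whether that probe set reads the transgene is not known here, so it cannot decide whether the arms were opposite. In the elongation zone 186 probe sets moved in opposite directions, 164 of them higher in upb1-1 and lower in OX and 22 the reverse. Another 575 moved in the same direction. Independent lists would share 210.1 in opposite and 210.2 in the same direction. The 210.1 pools both opposite directions, while the 164 and the 22 differ widely. It therefore gives no measure for either of them alone. The genes with the largest opposite changes were PER7 (3.66 in upb1-1 and -2.51 in OX), EXPA18 (3.62 and -1.91), PER44 (3.36 and -2.05), AT1G19900 (2.90 and -2.21), EXPA7 (2.64 and -2.17), AT4G16563, AT2G34810 and AT3G23090. The count of 186 was 57 and 80 without Col-0 replicate 1 or 2, 444 and 96 without upb1-1 replicate 1 or 2, 84 without OX replicate 1, and 75 when only these arrays were fitted.

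In the meristematic zone, 0 probe sets moved in opposite directions in limma, with 264 and 8926 at an unadjusted p below 0.05 in the separate comparisons, and all 6 probe sets that changed in upb1-1 changed in the same direction in OX, against the same Col-0 arrays, where independent lists would share 1.46. Across probe sets, the changes correlated by -0.02 in the meristematic and 0.22 in the elongation zone, against 0.47 and 0.45 in simulations of unchanged groups that share the Col-0 arrays. The covariance was -0.00563 against a simulated 0.0238 in the meristematic zone, a difference of -0.0294, and 0.0697 against 0.0433 in the elongation zone, a difference of 0.0264. With a pooled spread the differences were -0.0391 and 0.0365. With 1 Col-0 array for each comparison, an alternative chosen after seeing the data, the correlation was -0.12 and -0.09 in the meristematic zone, and -0.03 and 0.19 in the elongation zone, by which array served which comparison. In the simulations a mean of 0.02 probe sets was called in the same direction in the elongation zone and 0 in the meristematic zone. In opposite directions the mean was 0 in both zones. Those groups were unchanged, so few calls could arise, and the counts do not measure the part of the overlap that shared arrays bring. The overlap of calls was not split by control array, so part of it may come from the shared arrays. By the labels OX also lies in the upb1-1 background. Changes in the same direction may therefore follow from that shared background as well, which was not tested.

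The comparison of zones asks how expression differs between the pieces cut as the meristematic and as the elongation zone. On the mean of the 3 genotypes, single peroxidase and wall genes went both ways, and the tested cell division genes were lower in the elongation zone. PER21 rose by 3.09 (log2, SE 0.18, adjusted p = 3.6e-09), PER39 by 2.53, PER57 by 1.98 and PER40 by 1.98, while PER26 fell by 2.92. The mean hid differences between genotypes: PER57 changed by -0.04 in Col-0 (adjusted p = 0.889), 0.98 in upb1-1 and 5.01 in OX, whose meristematic arrays were low. EXPA8 rose by 2.50 and EXPA4 fell by 2.72. AUR2 fell by 2.32, BUBR1 by 1.99, AUR1 by 1.45, BBM by 1.68, ICU2 by 1.33 and PRL by 1.12. Control ratios were higher on the elongation than on the meristematic arrays of Col-0 (3.93 and 2.22) and upb1-1 (4.04 and 2.04), and not of OX (3.97 and 4.17).

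In total 10549 probe sets differed between zones on the mean of the genotypes, 4759 higher and 5790 lower in the elongation zone, and 1406 were higher and 2011 lower in each of the 3 genotypes. Higher and lower calls were 2767 and 3615 in Col-0, 3820 and 4509 in upb1-1, and 3790 and 4680 in OX. The count in Col-0 was 4015 without Col-0 meristematic replicate 1. The share of higher calls depended on the scaling, with 45.1% on the mean, 53.0% after quantile normalization and 61.7% after median centring. It was 43.4%, 52.7% and 65.2% in Col-0, 45.9%, 52.2% and 61.1% in upb1-1, and 44.7%, 51.0% and 57.8% in OX. The median change of all probe sets moved alike, from -0.05 on the mean to 0.06 and 0.20.

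Of the class III peroxidases, 16 were higher and 6 lower in the elongation zone on the mean of the genotypes, also adjusted over the list alone (adjusted p = 0.00871, and 0.152 with an estimated correlation). In Col-0 alone 9 were higher and 8 lower, and the list median of -0.04 was 0.00 after quantile normalization and 0.23 after median centring. All 3 UPB1-linked peroxidases rose, also adjusted over the list alone, a list chosen by the study on these samples and so not independent evidence (set adjusted p = 0.00406, and 0.0786 with an estimated correlation). All 5 xyloglucan endotransglucosylase/hydrolases rose, also adjusted over the list alone (adjusted p = 0.00431, and 0.155 with an estimated correlation), with XTH21 higher by 2.14 and XTH16 by 2.05. In Col-0 alone 2 of them were higher and 1, XTH18, lower (-1.09; median 0.14, adjusted p = 0.52), in upb1-1 the set did not pass (median 0.70, adjusted p = 0.0988), and in OX the median was 3.22 (adjusted p = 0.000153, and 0.0804 with an estimated correlation). Of 9 expansins 3 were higher and 4 lower, also adjusted over the list alone, and the set did not pass (adjusted p = 0.519). All 3 G2/M genes fell, also adjusted over the list alone (set adjusted p = 0.017, and 0.185 with an estimated correlation). Of 3 NADPH oxidases, RBOHE was higher by 0.49, also adjusted over the list alone, and the set did not pass (adjusted p = 0.479). That call was lost without 6 of the 12 arrays taken singly, with 0.32 (adjusted p = 0.0979) without upb1-1 elongation replicate 2. The largest fall by the naming rule was that of AT1G50060 (-5.36).

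The markers of xylem (13 genes), root cap (4 genes) and the cytokinin and auxin list (16 genes) had no member with a named and tested probe set, so these lists gave no result. The lists of antioxidant enzymes, glutathione S-transferases, DNA replication, root hairs, stem cell niche, endodermis, photosynthesis and wounding had 1 or 2 tested members each and are given by gene.

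Averaged over both zones, 627 probe sets differed between upb1-1 and Col-0, 396 higher and 231 lower, including UPB1. The share of higher calls was 63.2%, and 46.8% after median centring. Of the class III peroxidases 4 were higher, and 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.000408, and 0.0786 with an estimated correlation). The count of 627 depended on single arrays: it was 120, 112, 86 and 1204 without Col-0 meristematic replicate 1 or 2 or elongation replicate 1 or 2, and 101, 66, 3099 and 184 without the corresponding upb1-1 arrays. OX differed from Col-0 in 7398 probe sets, 3826 higher and 3572 lower, and from upb1-1 in 8029, 4260 higher and 3769 lower, with 20 and 19 class III peroxidases lower and 1 and 2 higher. Adjusted over the list alone 20 were lower and 2 higher in each (adjusted p = 2.94e-07 and 8.76e-08, and 0.0628 for both with an estimated correlation). These averages include the OX meristematic arrays with their higher 3' to 5' ratio.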

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

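In this part, the tests of elongating tissue in the OX meristematic pieces, of upb1-1 elongation pieces reaching further from the tip, of the transgene and of the UPB1 probe set, the tests of the probe sets changed alike in both zones, and the splits with even strata, were chosen only after the result was seen.

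The effects of genotype differed between zones by a test of the interaction for 359 probe sets in upb1-1 against Col-0, 3803 in OX against Col-0 and 4151 in OX against upb1-1. Of the 359, 65.5% were higher, against 52.4% after median centring. The counts depended on single arrays: the 359 were 59, 137, 86 and 745 without Col-0 meristematic replicate 1 or 2 or elongation replicate 1 or 2, and 69, 95, 2403 and 168 without the corresponding upb1-1 arrays. The 3803 were 2361 and 2489 without Col-0 meristematic replicate 1 or 2, and the 4151 were 2623 and 2660 without upb1-1 meristematic replicate 1 or 2. The OX meristematic arrays behind the 3803 and 4151 had a control ratio of 4.17, against 2.22 for Col-0 and 2.04 for upb1-1, while the elongation arrays had 3.97, 3.93 and 4.04.

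For upb1-1 against Col-0 the effect in the elongation zone exceeded that in the meristematic zone by 5.33 (log2) for PER35, 3.59 for PER44 and 3.56 for AT3G12540, and differed by -3.65 for AT5G35940 and -4.76 for AT3G55920. For OX against Col-0 the differences were 5.05 for PER57, 4.28 for AT1G62480, 4.03 for AT4G25250, 3.76 for AT5G46230 and -4.02 for AT3G55920. For OX against upb1-1 they were 5.06 for AT1G62480, 4.49 for AT4G25250, 4.42 for AT1G12080, 4.28 for AT5G46230 and 3.61 for XTH16.

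Many probe sets, 7834, differed between OX and Col-0 in the meristematic zone. A compressed signal, with bright probe sets falling and dim ones rising, is argued against as the whole source, since 38.77% of the 3160 changed probe sets in the brightest tertile were higher in OX (72.1% in the dimmest). The 3' to 5' control ratio was 1.946 (log2) higher in OX than in Col-0. Lower RNA quality, whether before or through the amplification, and an effect of genotype cannot be told apart here, because the ratio follows the group. The bound set before the values were seen compared the OX meristematic arrays with all 10 others and was met by 4.116 against 4.117, a difference below the replicate spread, but it was wrongly set, since the elongation arrays share the high ratio and the other meristematic arrays lie between 1.98 and 2.27. Lower RNA quality as the source of the excess of probe sets changed alike in the elongation zone (ratio difference 0.04257) is argued against by 1381 alike for 144 opposite, a ratio of 9.59 (4.34 to 13.4 by brightness tertile, 6.37 to 13.9 without 1 array, with 645 alike without Col-0 elongation replicate 1 and 517 without OX elongation replicate 1), but independent lists would share 551, so for single members it cannot be told apart from the genotype, and less elongating tissue in the OX pieces cannot be told apart from the genotype (0.01168, 95% interval -0.0399 to 0.0752), because the upb1-1 zone comparison behind that test spans the same ratio difference.

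In the elongation zone, 2979 probe sets differed between upb1-1 and Col-0, with 531 without Col-0 replicate 1, 722 without upb1-1 replicate 2 and 4745 without upb1-1 replicate 1. Lower RNA quality is argued against by a ratio difference of 0.1101. Probe sets that rose in upb1-1 lay 1.031 (log2) above those that fell in the zone effect of OX. The 95% interval was 0.948 to 1.12 over resampled probe sets, with the arrays held fixed. The OX arrays behind this zone effect are in neither group. Pieces of upb1-1 that reach further from the root tip are therefore a candidate explanation. The difference between the upb1-1 elongation replicates correlated with that zone effect by -0.3942 and that of the Col-0 elongation replicates by -0.318, against -0.046 and -0.0367 for the meristematic ones, so cutting positions may differ between samples, a bound written before this value but after correlations between replicate deviations were seen. A shift of expression along the root axis caused by loss of UPB1 would move the same genes and stays open, untested.

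The UPB1 signal on the OX-labelled arrays was near that of upb1-1. Between OX and upb1-1, 3828 probe sets differed in the elongation zone, more than the bound of that test asked for. The count cannot decide whether these arrays carry upb1-1 samples without the transgene. Pieces cut at different positions could also differ in many probe sets. A UPB1 probe set outside the transgene transcript cannot be told apart from a low transcript level (OX above upb1-1 by 0.9958, log2, SE 0.183), because the probe sequences are not used here, and the bounds of that test were set after its value was known. Another line under the OX label stays open.

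Other splits of the samples were counted with a model of 1 group difference. For the zones, 1 of the 100 drawn splits (the real one, of 462 possible) gave as many probe sets. It gave 8874 against at most 3766 in the others, or 2820 in 100 drawn splits that hold the genotypes evenly. A chance split is argued against by a share of 0.01, the smallest that 100 splits can give. The splits do not speak about differences that follow the zones, such as the 3' to 5' ratio on Col-0 and upb1-1 arrays. For OX against Col-0 and OX against upb1-1, 1 of 34 splits did, with 4481 and 4895 against 0. Only 18 of these splits hold the zones evenly, too few for a share under 0.05. For upb1-1 against Col-0, 1 of 34 splits did, with 1 probe set against 0, counts too low to speak about chance for the 627 of the fit of 12 arrays.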

How the results depend on the processing

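Fits of the elongation arrays alone, fits without the OX meristematic arrays, and the restriction to probe sets changed alike in both zones were tests chosen only after the result was seen.

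Of 234 gene and 58 list results, most kept their direction and side of the threshold: 271 at a pseudocount of 1 (21 weaker), 289 at 64 (3), 280 with no filter (12), 286 with no trend (6), 261 at the 60th percentile (0), 288 after median centring (4), 291 after quantile normalization (1) and 178 with only the arrays compared (15). With elongation arrays alone 84 did (12 weaker), and without the OX meristematic arrays 126 (4 weaker and 1 reversed). Without 1 array each, 1545 did, 129 were weaker, 1 stronger and 1 reversed. The lone array of a group is then assumed to vary like the other groups.

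At a pseudocount of 1, 220 probe sets differed between upb1-1 and Col-0 over both zones (627 in the report) and 118 in the interaction (359), which was 557 at a pseudocount of 64. With no filter the 2 counts were 202 and 148, with 123 opposite in the elongation zone (186), and with no trend 334 and 215. The cause was not tested. Fits of only the arrays compared have fewer residual degrees of freedom and take the spread from those arrays alone. That spread (SD, log2) was 0.20 on upb1-1 and 0.22 on Col-0 meristematic arrays. On the elongation arrays it was 0.36 and 0.30. In these fits 16 probe sets differed between upb1-1 and Col-0 in the meristematic (6) and 757 in the elongation zone (2979). Between OX and upb1-1 in the elongation zone 1866 differed (3828), and 75 were opposite. With elongation arrays alone the counts were 1263, 780 for OX against Col-0 (2234), 2230 and 75. Of the 7834 of OX against Col-0 in the meristematic zone 1381 changed alike in the elongation zone, by construction fewer. Of the 96 tests of fixed lists 56 passed with the preset and 0 with the estimated correlation (limma camera).

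Without 1 array each, upb1-1 against Col-0 gave 3 to 4 in the meristematic zone, 531 to 4745 in the elongation zone, 66 to 3099 over both zones and 59 to 2403 in the interaction. OX against Col-0 gave 781 to 1588 in the elongation zone and 2361 to 3493 in the interaction, OX against upb1-1 1758 to 5321 and 2623 to 4641, the zones of Col-0 4015 to 5288, and opposite changes in the elongation zone 57 to 444. The class III peroxidase median between the zones of Col-0 (-0.04) ran from -0.13 without Col-0 elongation replicate 2 to 0.10 without replicate 1, and the direction of its test was reversed in the latter and without the OX meristematic arrays (-0.0433), neither passing. The cause was not tested.

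Over 15 pairs of groups, deviations correlated between -0.151 and 0.277 (median 0.00653), so no pairing by replicate number ran through all groups. The highest value was that of the Col-0 and upb1-1 elongation arrays, and the lowest that of the Col-0 and OX elongation arrays. A replicate effect shared by the Col-0 and upb1-1 elongation arrays therefore stays open. With the replicate number as a replicate block 291 gene and list results kept their call and LHCB4.1 in OX meristems lost it (-0.69, adjusted p = 0.0538). With the plant pool as a random block (consensus correlation 0.00129) 292 did. Signal near the floor limits dim probe sets, whose log2 changes the added 16 compresses.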

Other observations

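The tests of root hair type genes and of plastid-encoded genes were chosen only after the result was seen, and the other lists in this part, apart from the fixed markers, were drawn up after the counts of changed probe sets were seen but before the values of their members were.

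Cytosolic ribosomal proteins (123 genes tested) fell in upb1-1 against Col-0 in the elongation zone, 73 lower and 0 higher in limma and 87 lower adjusted over the list alone, with a median of -0.84 (adjusted p = 1.12e-21, and 0.542 with an estimated correlation). Core histones (8 genes) had 6 lower and a median of -0.82 (adjusted p = 0.00135, and 0.534 with an estimated correlation). Mitotic kinesins with B-type cyclins (11 genes) had 2 lower and a median of -0.46 (adjusted p = 0.0471, and 0.555 with an estimated correlation). Between zones on the mean of genotypes, 106 ribosomal, 5 histone and 10 kinesin and cyclin genes were lower, with medians of -0.92, -0.82 and -1.77. The histone median was -0.79 in Col-0, -1.57 in upb1-1 and -0.14 in OX, and that of OX became 0.09 after median centring. On Col-0 and upb1-1 arrays the 3' to 5' ratio was also higher in the elongation zone. In OX against Col-0 in the meristematic zone, where the 3' to 5' ratio differs, 41 ribosomal genes fell and 10 rose. The 2979 probe sets of the upb1-1 comparison were 531 without Col-0 replicate 1.

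Of 18 families that share a symbol stem, TBL genes (19 tested) had 11 lower and 2 higher in OX against Col-0 in the meristematic zone (median -1.04, adjusted p = 0.00321, and 0.471 with an estimated correlation) and 8 higher and 1 lower in upb1-1 against Col-0 in the elongation zone (0.55, adjusted p = 0.0136, and 0.471). UGT genes (34 tested) had 6 higher and 2 lower in the latter (0.27, adjusted p = 0.0442, and 0.471). No family passed with an estimated correlation.

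Genes named here for their pattern across groups, after their values were seen, were higher on the Col-0 meristematic than on the Col-0 elongation arrays and near the floor on the OX meristematic arrays. PER35 had signals of 251 and 5.22 in the Col-0 zones and EXPA18 350 and 65.6. A hypothesis is that Col-0 and upb1-1 meristematic pieces hold tissue from further up the root that the OX pieces lack. In the change of upb1-1 against Col-0 in the elongation zone, probe sets that fell in OX meristems lay 0.09668 (log2) above those that rose. The 95% interval was 0.0753 to 0.13 over resampled probe sets, with the arrays held fixed. That hypothesis cannot be told apart from an effect of UPB1, because the loss of UPB1 and its overexpression, as labelled, would give the same sign.

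Plastid-encoded genes (68 tested) had 15 higher and 0 lower in limma in OX against Col-0 in the elongation zone, and 20 higher adjusted over the list alone (adjusted p = 4.73e-07, and 0.542 with an estimated correlation). Leaving out the 3 that had drawn attention, 65 genes had a median of 0.4132, with 12 higher and 53 above 0 (p = 3.54e-07 with the preset and 0.131 with the estimated correlation in limma). Higher plastid transcripts as a set cannot be told apart from correlated noise between genes, because the result turns on the correlation assumed. In the meristematic zone 34 of the 68 fell and 4 rose in OX, where the 3' to 5' ratio was higher.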
